A study of Homo sapiens with 12 samples.

How the data were processed

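Total RNA of 3 sublines of MCF7, an estrogen receptor positive human breast carcinoma line, was measured by the authors on the Affymetrix Human Transcriptome Array 2.0, a 1-colour array with probe sets for coding and noncoding transcripts. Per the labels, MCF7-F was kept in normal fetal bovine serum, MCF7-B was exposed chronically to bisphenol A and MCF7-G was exposed chronically to genistein. All cells were then kept for 72 h in medium without phenol red and with 5% charcoal-stripped serum, and received ethanol or 10 nM estradiol for 3 h. The 6 combinations of line and treatment had 2 arrays each, 12 in all, and the group and replicate number of every array came from its label. The labels gave neither the concentrations nor the durations of the chronic exposures.

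The deposited values were log2 signals, 1 per probe set and array, already normalized by the authors. The scale was read from the values, which ran from 1.30 to 14.3 with near-equal quartiles on all 12 arrays. Per the submitters' processing notes the values were made with Affymetrix Expression Console. Its version, the summarisation algorithm, the background correction and the genome build were not given in the sources used here. A summarisation that works across arrays would compress small differences near the background, so fold changes of dim genes are the least certain.

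The table held 70523 probe sets. The platform annotation listed exactly 1 gene symbol for 23781 of them, several symbols for 1543 and no gene for 45199. A probe set with no listed gene was unnamed here, and a probe set with several symbols was not used to name a gene. Symbols were updated through a RefSeq gene table of the GRCh38.p14 assembly, which served for gene names and gene order only. The update went by gene ID for 21497 probe sets and by symbol alone for 1974, and 310 symbols were kept as listed. For each of 22465 genes the probe set with the highest mean over the 12 arrays was taken. Of these genes 479 had more than 1 probe set, and 2995 probe sets of the table were not named as transcript clusters. A transcript cluster can pick up close paralogs, so the values of CEACAM5 and CEACAM6, of AKR1C2 and AKR1C3, and of ID2 and its pseudogene ID2B are open to cross-hybridisation. ERBB2 was among the genes to be reported but had no probe set with a single symbol, so it was not analysed here.

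Differences were estimated on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). One model with a mean for each of the 6 groups was fitted to all 12 arrays, with no replicate block, 6 residual degrees of freedom and 5.41 prior degrees of freedom. The contrasts were estradiol against ethanol in each line and averaged over the lines, each pair of lines in ethanol, and the 3 differences between the lines' estradiol responses. P-values were two-sided and adjusted with the Benjamini-Hochberg method over the 22465 genes of each comparison, with a threshold of 0.05. Errors given with ± are standard errors of the log2 difference from this model, with 2 arrays per group. No filter on dim genes was applied.

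Gene lists were tested with limma's camera, with the preset inter-gene correlation of 0.01 and again with a correlation estimated from the arrays, adjusted over the 22 lists of a comparison. The lists held 617 members, of which 523 were measured. Over all 10 comparisons 81 lists passed with the preset correlation, and 12 of these also passed with an estimated one. Counts of members were made after adjustment over all genes and adjusted over the list alone. The overlap of MCF7-B and MCF7-G against MCF7-F was set beside 100 simulations of unchanged groups that shared the 2 control arrays, with noise independent across genes and arrays. It was also set beside the overlap of independent lists.

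The groups, comparisons, tests, gene lists, alternative settings and the rule for named genes were fixed before the data were examined, except for those named below as chosen afterwards. The rule took, in each comparison, the 8 largest rises and the 8 largest falls past the threshold in which both arrays of one group lay above both of the other. For the average over lines this had to hold in at least 2 of the 3 lines, and for the differences between responses 5 genes each way were taken with no such condition. It added up to 4 members per list by smallest p, or at most 2 as values only where none passed, and 10 measured genes in every estradiol and line comparison. Provisional, locus-style and small RNA symbols were not eligible. Both text and plots follow this rule, with any other gene named as chosen after its values were seen.

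The model was tested on simulated values for estradiol against ethanol in MCF7-F, over 22465 genes with independent noise. Of 50 genes changed by each fold it recovered 22% at 1.25-fold, 84% at 1.5-fold and 100% at 2-fold and at 3-fold, with 4 false calls among 22265 unchanged genes. Alternatives were another value per gene, every probe set on its own, a filter on dim genes, centring, quantile normalization, another prior, only the groups compared, the replicate number as a block, other thresholds, and each array left out in turn. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision. The labels call the experiment duplicate without saying that replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.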

Results

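The data were the expression values of 22465 named genes on 12 arrays, 2 for each of MCF7-F, MCF7-B and MCF7-G in ethanol and in 10 nM estradiol. Estradiol acted for 3 h after 72 h in charcoal-stripped serum, so the comparisons concern early changes. Bisphenol A is an industrial plastics monomer and genistein is a soy isoflavone, and both bind estrogen receptors. Array medians lay between 6.21 and 6.31 on the log2 scale, and the replicates of a group correlated across genes with r from 0.993 in MCF7-B estradiol to 0.998 in MCF7-G estradiol. The SD of the difference between replicates was largest in MCF7-B estradiol, at 0.218, and smallest in MCF7-G estradiol, at 0.107. The mean of 262 small nucleolar and nuclear RNAs, relative to its mean over arrays, was -0.20 and -0.18 on the 2 MCF7-F ethanol arrays and lay between -0.04 and 0.15 on the other 10 arrays.

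The first comparison asked what estradiol did in MCF7-F, the line kept in normal serum. PGR, the progesterone receptor, rose most, by 1.87 ± 0.19 on the log2 scale (standard error, 2 arrays per group, 3.65-fold, adjusted p = 0.000368). MYBL1, a MYB-family transcription factor, rose by 1.65 ± 0.17, RASGRP1, a Ras activator, by 1.47 ± 0.12, and GREB1, an early estrogen target, by 1.47 ± 0.20 (adjusted p = 0.00209). The kinase JAK2 rose by 1.36 ± 0.15, the small GTPase RAB31 by 1.33 ± 0.10, the receptor tyrosine kinase RET by 1.33 ± 0.10 (adjusted p = 8.78e-05) and SYTL5, a vesicle trafficking protein, by 1.31 ± 0.09. Among genes that met the naming rule, the largest falls were those of RNF43, a ubiquitin ligase that restrains Wnt receptors (-1.13 ± 0.12, adjusted p = 0.000581), the protocadherin PCDH10 (-0.87 ± 0.11) and ID2B (-0.86 ± 0.09). The largest fall of any called gene was -1.41. KITLG (-0.79 ± 0.13), FAM83B (-0.76 ± 0.11), TNFRSF11B (-0.75 ± 0.13), ID2 (-0.73 ± 0.13) and FTX (-0.72 ± 0.12) also fell. Of the genes reported in every comparison, MYC rose by 1.03 ± 0.10, the chemokine CXCL12 by 1.20 ± 0.11, cyclin D1 (CCND1) by 0.67 ± 0.10 and the secreted trefoil peptide TFF1 by 0.48 ± 0.10 (adjusted p = 0.0352). The estrogen receptor gene ESR1 (-0.23 ± 0.08, adjusted p = 0.25), EGR3 (0.26 ± 0.11), FOXA1 (0.14 ± 0.08) and GATA3 (-0.20 ± 0.10) did not pass. In all 461 genes passed, 402 higher and 59 lower. Of the genes named so far that passed, 7 did not pass without an array, with the largest adjusted p for KITLG (0.0752) and FAM83B (0.0511) without ethanol replicate 2, TNFRSF11B (0.137) and CCND1 (0.0739) without estradiol replicate 1, ID2 (0.124) without estradiol replicate 2, and FTX (0.0936) and TFF1 (0.305) without ethanol replicate 1.

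**Figure D1:**
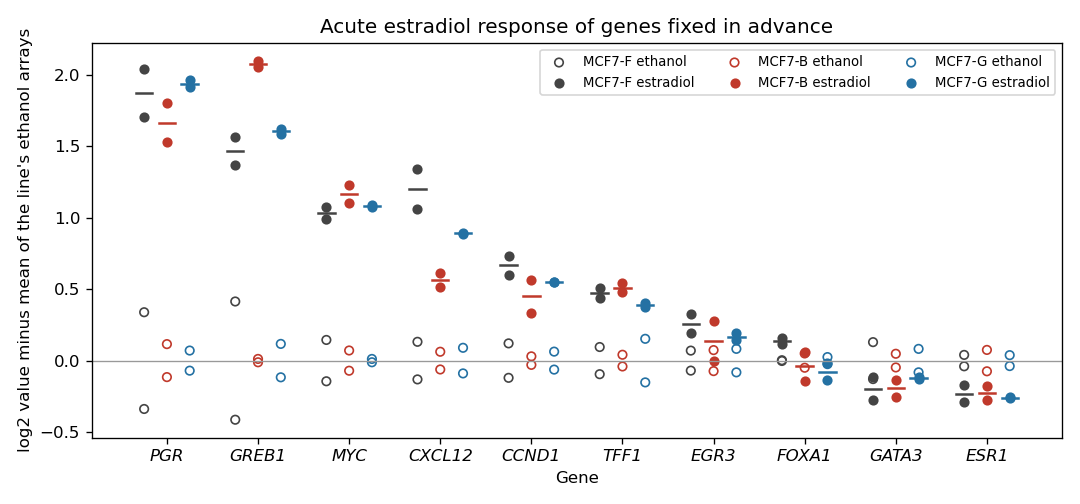
Log2 value of each array minus the mean of the same line's ethanol arrays (vertical axis) for 10 genes reported in every comparison (horizontal axis). Open circles are ethanol arrays, filled circles are estradiol arrays, bars are means of the 2 estradiol arrays, and colours mark the lines. PGR, GREB1 and MYC lie far above the ethanol arrays in all 3 lines, with PGR at 1.87, 1.66 and 1.94 in MCF7-F, MCF7-B and MCF7-G, while the means of FOXA1, GATA3 and ESR1 lie between -0.26 and 0.14.

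The list of estrogen-induced genes rose together in MCF7-F. Of its 47 measured members 35 rose and none fell (39 and 0 adjusted over the list alone), among them carbonic anhydrase CA12 (1.11 ± 0.08), RET, RASGRP1 and the ubiquitin ligase SIAH2 (1.03 ± 0.09). This list had adjusted p = 0.00536 with an estimated correlation. Of 26 ribosome biogenesis and MYC target genes 11 rose and none fell (20 and 0 adjusted over the list alone), including NOP16 (0.75 ± 0.07), RRS1 (1.04 ± 0.13), WDR43 (0.73 ± 0.09) and NIP7 (0.67 ± 0.09). Camera gave this list adjusted p = 0.00536 with an estimated correlation. Of 23 estrogen-repressed genes 3 fell and 1 rose (5 and 1 adjusted over the list alone). Those that fell were the cell cycle inhibitor cyclin G2 (CCNG2, -0.56 ± 0.08), the stress-induced TP53INP1 (-0.68 ± 0.10) and EFNA1 (-0.46 ± 0.07), while IER3 rose (0.55 ± 0.11). The call for this list, downward with the preset correlation, had adjusted p = 0.162 with an estimated correlation. The largest adjusted p with 1 array left out was at or above the threshold for CCNG2 and NIP7 (0.05 each) without estradiol replicate 1, TP53INP1 (0.0539) without estradiol replicate 2, and EFNA1 (0.0772) and IER3 (0.152) without ethanol replicate 2.

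A further 11 lists passed upward with the preset correlation in MCF7-F, and none of these did with an estimated one. Of 27 ERBB and IGF signalling genes 6 rose and 1 fell (8 and 2 adjusted over the list alone), including the adaptor GAB2 (0.90 ± 0.07), the EGFR ligand TGFA (0.70 ± 0.07) and IGFBP4 (0.96 ± 0.11). For these members together camera gave adjusted p = 0.0938 with an estimated correlation. Of 27 immediate early genes 3 rose and none fell (8 and 1 adjusted over the list alone), namely PHLDA1 (0.73 ± 0.07), FOSL2 (0.56 ± 0.08) and IER3. The list test had adjusted p = 0.541 with an estimated correlation. Of 22 receptor, cofactor and luminal identity genes TFAP2C (0.56 ± 0.08), KRT19 (0.49 ± 0.09) and AGR3 (1.09 ± 0.21) rose and the membrane estrogen receptor GPER1 fell (-0.37 ± 0.08), which made 8 and 4 adjusted over the list alone. As a set they had adjusted p = 0.616 with an estimated correlation. Of 24 hypoxia and glycolysis genes the glucose transporter SLC2A1 (0.71 ± 0.11) and hexokinase HK2 (0.49 ± 0.09) rose, 4 and 0 adjusted over the list alone. This list had adjusted p = 0.15 with an estimated correlation. In the S phase list 1 of 27 members rose (CDC25A, 0.48 ± 0.08, also 1 adjusted over the list alone), in the unfolded protein list 1 of 25 (STC2, 0.90 ± 0.11, 2 adjusted over the list alone) and in the cholesterol synthesis list 1 of 19 (DHCR7, 0.51 ± 0.10, 2 adjusted over the list alone). Each of these 3 lists had adjusted p = 0.295 with an estimated correlation, and the median of the cholesterol list turned from 0.07 to -0.000788 after quantile normalization. In the heat shock list FKBP4 rose (0.58 ± 0.09, 1 of 16 and 1 adjusted over the list alone), and none of 23 ribosomal protein genes passed, also adjusted over the list alone. Both of these lists had adjusted p = 0.434 with an estimated correlation, and the median of the ribosomal proteins turned from 0.06 to -0.00773 after quantile normalization. Neither the 19 NRF2 targets and metallothioneins (adjusted p = 0.632 with an estimated correlation) nor the 17 histones (adjusted p = 0.626 with an estimated correlation) had a member past the threshold, over all genes or adjusted over the list alone. Their medians of 0.10 and 0.06 turned to -0.04 and -0.02 without MCF7-F ethanol replicate 1. The members TFAP2C, KRT19, AGR3, GPER1, SLC2A1, CDC25A, DHCR7 and FKBP4 did not pass without MCF7-F estradiol replicate 1, with adjusted p from 0.0512 (TFAP2C) to 0.316 (GPER1). HK2 had at most 0.174, without MCF7-F ethanol replicate 1, and IER3 at most 0.152, without MCF7-F ethanol replicate 2.

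The 8 other lists did not pass in MCF7-F. The count of members that rose and fell, the same adjusted over the list alone unless given, was 1 and 0 of 18 basal and mesenchymal markers (CD44, 0.50 ± 0.08), 0 and 0 of 16 markers of non-epithelial cells, 0 and 0 of 27 mitosis genes and 0 and 0 of 27 interferon response genes. It was 0 and 1 of 38 xenobiotic genes (the exporter ABCC5, -0.62 ± 0.09, with 1 and 1 adjusted over the list alone), 1 and 1 of 21 p53 targets (AEN, 0.53 ± 0.08, and TP53INP1, with 2 and 1 adjusted over the list alone), 2 and 0 of 18 cell death genes (BCL2, 0.79 ± 0.09, and TNFRSF10A, 0.37 ± 0.08) and 1 and 0 of 28 chromatin regulators (the demethylase KDM4B, 0.40 ± 0.08). CD44 (adjusted p 0.125) and AEN (0.0834) did not pass without estradiol replicate 1, and TNFRSF10A (0.155), KDM4B (0.133) and TP53INP1 (0.0539) did not without estradiol replicate 2. Of the 262 small RNAs, low on both MCF7-F ethanol arrays, 36 were higher in estradiol and none was lower in MCF7-F, with a median of 0.17. In MCF7-B 1 was higher and 1 lower (median -0.03), and in MCF7-G 3 were higher and none lower (median -0.01). The share of calls that were higher was 87.2% as deposited and 75.4% after quantile normalization. Without MCF7-F ethanol replicate 1 or 2 the count of genes was 224 or 265, without MCF7-F estradiol replicate 1 or 2 it was 141 or 254. Centring the arrays gave 303, and only the groups compared gave 802.

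The same treatment was then asked of MCF7-B, the line exposed to bisphenol A. GREB1 rose most, by 2.07 ± 0.20 (adjusted p = 0.000762), followed by MYBL1 (1.86 ± 0.17), PGR (1.66 ± 0.19, adjusted p = 0.00171), CA12 (1.44 ± 0.08, adjusted p = 1.28e-05), the glycoprotein hormones STC2 (1.34 ± 0.11) and STC1 (1.24 ± 0.12), the signalling adaptor TIFA (1.29 ± 0.10) and the neuropeptide Y receptor NPY1R (1.26 ± 0.14). RNF43 fell by 1.12 on the log2 scale, the phospholipase LIPH by 0.97, the growth factor KITLG by 0.93, PCDH10 by 0.89, SLITRK6 by 0.88, TP53INP1 by 0.87, the transcription factor SOX2 by 0.84 and RNF144B by 0.83. MYC rose by 1.16 ± 0.10, while TFF1 (0.51 ± 0.10, adjusted p = 0.0409) and CXCL12 (0.56 ± 0.11, adjusted p = 0.0455) passed narrowly. CCND1 (0.45 ± 0.10, adjusted p = 0.079), ESR1 (-0.23 ± 0.08), EGR3 (0.14 ± 0.11), FOXA1 (-0.04 ± 0.08) and GATA3 (-0.19 ± 0.10) did not pass. Of 47 estrogen-induced genes 22 rose and none fell (34 and 0 adjusted over the list alone), with adjusted p = 0.0068 with an estimated correlation. Of 26 ribosome biogenesis and MYC targets 6 rose and none fell (14 and 0 adjusted over the list alone), including NOP16 (0.58 ± 0.07) and the RNA polymerase I subunit POLR1B (0.69 ± 0.10). Camera gave this list adjusted p = 0.0068 with an estimated correlation. Of 23 estrogen-repressed genes 6 fell and none rose (16 and 0 adjusted over the list alone), among them TP53INP1, the interleukin 1 receptor IL1R1 (-0.75 ± 0.09), CCNG2 (-0.61 ± 0.08) and NEDD9 (-0.43 ± 0.07). For these members together camera gave adjusted p = 0.00829 with an estimated correlation. The xenobiotic list, with 1 of 38 members lower (ABCC5, -0.56 ± 0.09) and 1 higher and 3 lower adjusted over the list alone, passed downward with the preset correlation and had adjusted p = 0.136 with an estimated correlation. The NRF2 and histone lists, with no member past the threshold over all genes or adjusted over the list alone, also passed downward, and each had adjusted p = 0.812 with an estimated correlation. The other 16 lists did not pass. In all 215 genes passed, 151 higher and 64 lower. Without MCF7-B ethanol replicate 1 or 2 the count was 63 or 61, without either MCF7-G estradiol array it was 134, and with only the 2 groups in the model it was 73, with centred arrays 87 and with every probe set tested 103. Without ethanol replicate 1 the named genes LIPH (adjusted p 0.0647), KITLG (0.069), SLITRK6 (0.122), SOX2 (0.0562), CCNG2 (0.0562), NEDD9 (0.137), ABCC5 (0.189), NOP16 (0.0551) and CXCL12 (0.379) did not pass, and without ethanol replicate 2 TFF1 (0.299) and POLR1B (0.0904) did not.

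In MCF7-G, the line exposed to genistein, the largest rises were those of MYBL1 (2.04 ± 0.17, adjusted p = 0.00019), PGR (1.94 ± 0.19), GREB1 (1.60 ± 0.20), TIFA (1.57 ± 0.10), CA12 (1.34 ± 0.08, adjusted p = 1.97e-05), the actin nucleator FMN1 (1.28 ± 0.11), the transcription factor MYB (1.26 ± 0.14) and AGR3 (1.25 ± 0.21). Among genes that met the naming rule, RNF43 fell by 1.44 on the log2 scale, the sialyltransferase ST8SIA4 by 1.22, KITLG by 1.16, the decoy receptor TNFRSF11B by 1.12, LIPH by 1.05, the glycosyltransferase GCNT4 by 1.00, PCDH10 by 0.93 and ID1, an inhibitor of differentiation, by 0.93. The largest change downward of any called gene was -1.48. MYC rose by 1.08 ± 0.10, CXCL12 by 0.89 ± 0.11 and CCND1 by 0.55 ± 0.10 (adjusted p = 0.0176). TFF1 (0.39 ± 0.10, adjusted p = 0.0986), ESR1 (-0.26 ± 0.08), EGR3 (0.17 ± 0.11), FOXA1 (-0.08 ± 0.08) and GATA3 (-0.12 ± 0.10) did not pass. Of 47 estrogen-induced genes 25 rose and none fell (36 and 0 adjusted over the list alone), with adjusted p = 0.015 with an estimated correlation. Of 26 ribosome biogenesis and MYC targets 8 rose and none fell (13 and 0 adjusted over the list alone), with adjusted p = 0.0199 with an estimated correlation. Of 23 estrogen-repressed genes 7 fell and none rose (15 and 0 adjusted over the list alone), including TP53INP1 (-0.85 ± 0.10), CCNG2 (-0.57 ± 0.08), IL1R1 (-0.63 ± 0.09) and SMAD6 (-0.62 ± 0.10). The list test had adjusted p = 0.0363 with an estimated correlation. The mitosis list (no member of 27 past the threshold, 1 lower adjusted over the list alone) and the histone list (none of 17 either way) passed downward with the preset correlation, and each had adjusted p = 0.416 with an estimated correlation. The other 17 lists did not pass. In all 391 genes passed, 214 higher and 177 lower. Without MCF7-G ethanol replicate 1 or 2 the count was 168 or 189, without MCF7-G estradiol replicate 1 or 2 it was 112 or 131, and without either MCF7-B estradiol array, the group with the widest spread, it was 590. Centring the arrays gave 187 and testing every probe set 258. Without estradiol replicate 1 the named genes AGR3 (adjusted p 0.131), GCNT4 (0.0925), CCND1 (0.165), CCNG2 (0.0567), IL1R1 (0.0704) and SMAD6 (0.135) did not pass.

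The estradiol calls of the lines were then set against each other. Of 450 genes rising in at least 1 line 123 rose in all 3, of 210 falling in at least 1 line 25 fell in all 3, and no gene passed in opposite directions in any pair of lines. With 1 array left out these counts went down to 38 rising, without MCF7-B ethanol replicate 2, and to 7 falling, without MCF7-B ethanol replicate 1 or MCF7-F ethanol replicate 2. The rising count was 47 without MCF7-B ethanol replicate 1, 62 or 63 without an MCF7-G estradiol array, and 74 to 78 without MCF7-B estradiol replicate 1, MCF7-F estradiol replicate 1 or MCF7-G ethanol replicate 2. The falling count was 8 without either MCF7-F estradiol array and 10 to 12 without MCF7-B ethanol replicate 2 or an MCF7-G estradiol array. Centring gave 51 and 9, only the groups compared 52 and 13. MCF7-F and MCF7-B shared 135 rising genes where 2.70 would be shared by independent lists, MCF7-F and MCF7-G shared 175 (3.83), and MCF7-B and MCF7-G shared 130 (1.44). The shared falling genes numbered 25 (0.168), 37 (0.465) and 53 (0.504) in the same order. Of the 402 genes rising in MCF7-F, 92.3% had a positive change in MCF7-B and 93.8% in MCF7-G, while 33.6% and 43.5% passed there. Of the 177 falling in MCF7-G, 98.9% had a negative change in MCF7-F and 20.9% passed there. Averaged over the lines, 727 genes rose and 517 fell. The largest rises were those of MYBL1 (1.85 ± 0.10), PGR (1.82 ± 0.11), GREB1 (1.71 ± 0.11), TIFA (1.38 ± 0.05), CA12 (1.30 ± 0.04, adjusted p = 9.03e-08), RASGRP1 (1.27 ± 0.07), NPY1R (1.21 ± 0.08) and FMN1 (1.20 ± 0.06), and the largest falls those of RNF43 (-1.23 ± 0.07), KITLG (-0.96 ± 0.07), PCDH10 (-0.90 ± 0.07), LIPH (-0.88 ± 0.08), ST8SIA4 (-0.88 ± 0.08), SOX2 (-0.80 ± 0.07), TP53INP1 (-0.80 ± 0.06) and ID2B (-0.73 ± 0.05). ESR1, which passed in no single line, fell on average by 0.24 on the log2 scale (adjusted p = 0.00935), while EGR3 (0.19 ± 0.06, adjusted p = 0.129), GATA3 (-0.17 ± 0.06) and FOXA1 (0.01 ± 0.05) did not pass. Of the estrogen-induced genes 37 rose and none fell (40 and 0 adjusted over the list alone, adjusted p = 0.00333 with an estimated correlation). Of the ribosome biogenesis genes 16 rose and none fell (20 and 0 adjusted over the list alone, adjusted p = 0.00333 with an estimated correlation). Of the estrogen-repressed genes 12 fell and none rose (17 and 2 adjusted over the list alone, adjusted p = 0.0163 with an estimated correlation). The S phase list passed upward (CDC25A, 0.35 ± 0.05, 1 of 27 higher, 1 adjusted over the list alone) and the histone list downward with no member past the threshold either way, each with adjusted p = 0.789 with an estimated correlation. The mitosis list passed downward (NDC80, -0.28 ± 0.07, with adjusted p 0.138 without MCF7-F ethanol replicate 2, 1 of 27 lower, 0 adjusted over the list alone). As a set they had adjusted p = 0.849 with an estimated correlation.

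**Figure D2:**
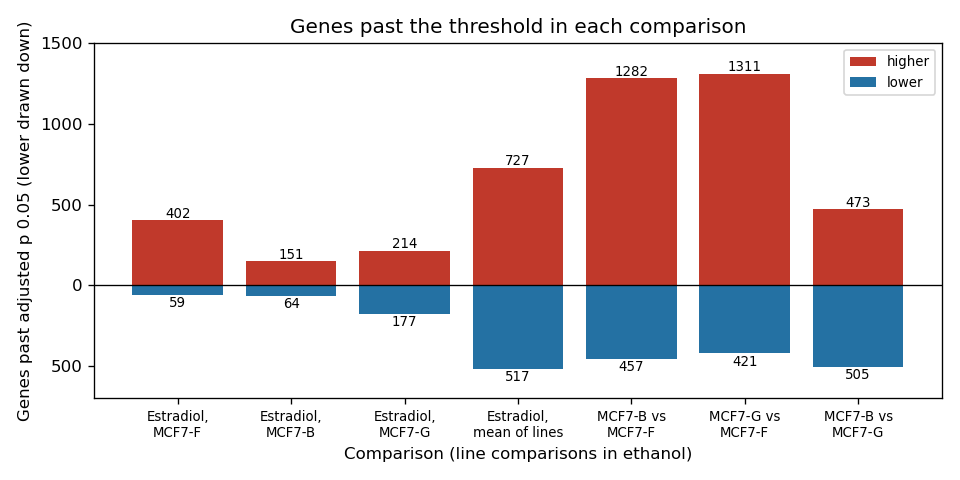
Number of genes past adjusted p 0.05 (vertical axis) in each estradiol comparison and each comparison between lines in ethanol (horizontal axis). Red bars count genes that were higher and blue bars, drawn downward, genes that were lower, with the counts printed at the bars. Both exposed lines differ from MCF7-F in more genes (1282 higher and 457 lower, 1311 higher and 421 lower) than estradiol changed in any single line.

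Whether the exposed lines responded otherwise to estradiol was asked with the difference between responses. With limma a single gene passed in each difference, and each was lost with 1 array left out. The response of SYTL5 was smaller by 1.26 ± 0.12 in MCF7-B than in MCF7-F (adjusted p = 0.0109, and 0.12 without MCF7-F ethanol replicate 1) and smaller by 1.09 ± 0.12 in MCF7-G than in MCF7-F (adjusted p = 0.0471, and 0.477 without MCF7-G estradiol replicate 1). The mean of SYTL5 went from 6.002 to 7.31 in MCF7-F, from 7.34 to 7.39 in MCF7-B and from 6.95 to 7.17 in MCF7-G. The response of CALCR, the calcitonin receptor, was smaller by 1.08 ± 0.12 in MCF7-B than in MCF7-G (adjusted p = 0.0338, and 0.376 without MCF7-G estradiol replicate 1), as its mean went from 5.18 to 5.05 in MCF7-B and from 5.34 to 6.30 in MCF7-G. Among members of the estrogen lists, the response in MCF7-B minus that in MCF7-F was -0.69 ± 0.14 for RET (adjusted p = 0.341), -0.84 ± 0.19 for the amino acid transporter SLC7A5 and -0.67 ± 0.14 for EPAS1. None of these passed, nor did GREB1 in MCF7-B minus MCF7-G (0.47 ± 0.28, adjusted p = 1). Unadjusted p was under 0.05 for 1290 genes in MCF7-B minus MCF7-F, 2175 in MCF7-G minus MCF7-F and 334 in MCF7-B minus MCF7-G. Independent noise would give 1123 in each. Replicate differences were correlated between groups (r up to 0.516), and 334 lies far under 1123. So 1123 is no sure chance level, and the 2175 cannot be counted as true differences. With the preset correlation 14 lists passed in MCF7-B minus MCF7-F and 15 in MCF7-G minus MCF7-F, all downward, with a smallest adjusted p = 0.291 with an estimated correlation in the first and a smallest adjusted p = 0.299 with an estimated correlation in the second. These 14 included both the estrogen-induced genes (median -0.16, 0 of 47 past the threshold and 4 lower adjusted over the list alone) and the estrogen-repressed genes (median -0.15, 0 of 23 and 3 lower adjusted over the list alone). In MCF7-B minus MCF7-G the mitosis list alone passed, upward (median 0.17, 0 of 27 past the threshold over all genes or adjusted over the list alone). This list had adjusted p = 0.873 with an estimated correlation. Both differences from MCF7-F contain the ethanol arrays with the low small RNA values, and the median difference of small RNAs was -0.21 and -0.19.

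Genes called with estradiol in one line were then followed in the other 2 lines, so that the calls came from arrays outside the comparison. The 64 genes falling in MCF7-B had a response more negative in MCF7-G than in MCF7-F by a median of 0.241, with a positive difference in 9.38% of genes (camera p = 1.4e-13, p = 0.0908 with an estimated correlation). The level of these genes in ethanol, given further below, uses the same ethanol arrays of both lines, so the 2 results are not independent. Of the 214 genes rising in MCF7-G 30.4% had a larger response in MCF7-B than in MCF7-F (median -0.09, p = 0.114 with an estimated correlation). Of the 177 falling in MCF7-G 25.99% had a positive difference (median -0.10, p = 0.385 with an estimated correlation). The 151 genes rising in MCF7-B had a median difference of -0.02 between MCF7-G and MCF7-F (46.4% positive, p = 0.891 with an estimated correlation). The 402 genes rising in MCF7-F had a median of -0.04 in MCF7-B minus MCF7-G (p = 0.237 with an estimated correlation) and the 59 falling had 0.07 (p = 0.411 with an estimated correlation). The first of these 2 medians turned to 0.00749 without MCF7-B estradiol replicate 2, and the second to -0.03 without MCF7-B estradiol replicate 1 and to -0.01 without MCF7-F estradiol replicate 2.

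The lines were next compared without estradiol. MCF7-B, against MCF7-F in ethanol, had higher levels of the cell adhesion glycoproteins CEACAM6 (3.22 ± 0.11, 9.30-fold, adjusted p = 1.18e-07) and CEACAM5 (2.65 ± 0.16), which are close paralogs. OTULINL (2.37 ± 0.14), CT83 (2.34 ± 0.27), the muscle protein nebulin (NEB, 2.30 ± 0.12), the sphingosine phosphatase SGPP1 (2.22 ± 0.12), the glycine receptor GLRA3 (2.22 ± 0.17) and the copper-carrying plasma protein ceruloplasmin (CP, 2.00 ± 0.10) were also higher. The largest decreases were those of DOCK10 (-1.86 ± 0.12), SCML1 (-1.70 ± 0.12), the transcription factor DACH1 (-1.66 ± 0.11), CA12 (-1.40 ± 0.08), thrombospondin 1 (THBS1, -1.29 ± 0.11), the kinase PRKD3 (-1.27 ± 0.12), the chaperone HSPA4L (-1.23 ± 0.12) and STC1 (-1.22 ± 0.12). ESR1 was lower in MCF7-B by 0.45 on the log2 scale (adjusted p = 0.00523, and 0.0576 without MCF7-B ethanol replicate 2), while FOXA1 was higher (0.39 ± 0.08, adjusted p = 0.0158, and 0.167 without MCF7-B ethanol replicate 1). PGR (-0.01 ± 0.19), GREB1 (-0.59 ± 0.20, adjusted p = 0.0942), CXCL12 (-0.41 ± 0.11, adjusted p = 0.0512), TFF1, MYC, CCND1, EGR3 and GATA3 did not pass.

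Among the lists, hypoxia and glycolysis genes were higher in MCF7-B than in MCF7-F. Of 24 members 9 were higher and 1 lower (13 and 1 adjusted over the list alone), including NDRG1 (0.89 ± 0.08), the oxidoreductase ERO1A (1.00 ± 0.10), the oxygen sensor EGLN3 (0.73 ± 0.07) and MXI1 (0.37 ± 0.07). Camera gave this list adjusted p = 0.0195 with an estimated correlation. The other 5 called lists did not pass with an estimated correlation. Of 38 xenobiotic metabolism genes 12 were higher and 2 lower (15 and 4 adjusted over the list alone), including the aldo-keto reductases AKR1C3 (1.47 ± 0.10) and AKR1C2 (1.29 ± 0.09), steroid sulfatase (STS, 1.10 ± 0.09) and the quinone reductase NQO1 (0.79 ± 0.08). For these members together camera gave adjusted p = 0.052 with an estimated correlation. Of 23 estrogen-repressed genes 8 were higher and 1 lower (13 and 3 adjusted over the list alone), including EPAS1 (1.64 ± 0.10), IL1R1 (1.56 ± 0.09), NEDD9 (0.76 ± 0.07) and the mucin MUC1 (1.15 ± 0.12). The list test had adjusted p = 0.122 with an estimated correlation. Of 27 S phase genes 10 were higher and none lower (17 and 0 adjusted over the list alone), including the flap endonuclease FEN1 (0.67 ± 0.08), thymidylate synthase (TYMS, 0.74 ± 0.09), MCM2 (0.50 ± 0.08) and PCNA (0.66 ± 0.11). As a set they had adjusted p = 0.187 with an estimated correlation. Of 26 ribosome biogenesis genes 4 were higher and none lower (7 and 0 adjusted over the list alone), including NOB1 (0.64 ± 0.10) and CAD (0.51 ± 0.08). This list had adjusted p = 0.261 with an estimated correlation. Of 27 interferon response genes 5 were higher and none lower (6 and 0 adjusted over the list alone), including SAMD9 (0.92 ± 0.15, a dim gene with means of 3.55 in MCF7-F and 4.47 in MCF7-B), IFIT1 (0.56 ± 0.10), OAS2 (0.41 ± 0.08) and IFI27 (1.07 ± 0.21). Camera gave this list adjusted p = 0.55 with an estimated correlation. The other 16 lists did not pass. Without MCF7-F ethanol replicate 1 MXI1 (adjusted p 0.0743) did not pass, and without MCF7-B ethanol replicate 1 IFI27 and OAS2 (0.0797 each) did not.

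The estrogen-induced list did not pass between MCF7-B and MCF7-F, with 3 of 47 members higher and 4 lower (4 and 10 adjusted over the list alone). CA12 and MYB (-0.92 ± 0.14) were lower, and the galactosyltransferase B4GALT1 (0.52 ± 0.07) and XBP1 (0.74 ± 0.11) higher. The luminal identity list did not pass either, with 6 of 22 higher and 4 lower (7 and 4 adjusted over the list alone), GPER1 at -1.11 ± 0.08, ELF3 at 0.60 ± 0.08 and E-cadherin (CDH1) at 0.45 ± 0.08 (adjusted p 0.0791 without MCF7-B ethanol replicate 1). In all 1739 genes passed, 1282 higher and 457 lower in MCF7-B. Small RNAs moved the same way, with 57 of 262 higher, none lower and a median of 0.19, and 73.7% of all calls were higher as deposited against 62.3% after quantile normalization. The count was 702 without MCF7-F ethanol replicate 1, 597 without MCF7-B ethanol replicate 1 and 1006 without MCF7-B ethanol replicate 2.

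MCF7-G, against MCF7-F in ethanol, had higher levels of CT83 (3.41 ± 0.27), the actin-bundling protein PLS3 (3.35 ± 0.12, adjusted p = 1.11e-07), NEB (3.00 ± 0.12), KLHL4 (2.50 ± 0.10), ST8SIA4 (2.36 ± 0.13), FSTL5 (2.32 ± 0.11), GCNT4 (2.15 ± 0.15) and PABPC4L (2.08 ± 0.09). Lower were SCML1 (-2.30 ± 0.12), CA12 (-1.52 ± 0.08, adjusted p = 7.77e-07), SLC7A5 (-1.43 ± 0.13), LRP12 (-1.26 ± 0.11), STC1 (-1.24 ± 0.12), the calcium-binding protein S100A9 (-1.23 ± 0.15), SYNPO2 (-1.18 ± 0.09) and RIMS2 (-1.16 ± 0.08). ESR1 (-0.12 ± 0.08, adjusted p = 0.425), PGR (0.32 ± 0.19), GREB1 (-0.13 ± 0.20), TFF1, MYC (-0.24 ± 0.10), CCND1, EGR3 and GATA3 did not pass. FOXA1 was higher (0.46 ± 0.08, adjusted p = 0.006, and 0.0593 without MCF7-G ethanol replicate 1) and CXCL12 lower (-0.46 ± 0.11, adjusted p = 0.0294, and 0.281 without MCF7-F ethanol replicate 1).

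For MCF7-G against MCF7-F 7 lists passed with the preset correlation and none with an estimated one. Of 38 xenobiotic metabolism genes 12 were higher and 1 lower (13 and 2 adjusted over the list alone), including AKR1C3 (1.21 ± 0.10), AKR1C2 (0.96 ± 0.09), STS (0.71 ± 0.09) and the aryl hydrocarbon receptor AHR (0.74 ± 0.09). For these members together camera gave adjusted p = 0.0965 with an estimated correlation. Of 23 estrogen-repressed genes 10 were higher and 1 lower (15 and 2 adjusted over the list alone), with IL1R1 (1.26 ± 0.09), MUC1 (1.14 ± 0.12) and NEDD9 (0.68 ± 0.07) higher and BAMBI (-1.02 ± 0.09) lower. The list test had adjusted p = 0.121 with an estimated correlation. Of 27 ERBB and IGF genes 6 were higher and none lower (6 and 1 adjusted over the list alone), including the receptors ERBB4 (1.49 ± 0.10) and ERBB3 (0.60 ± 0.08). As a set they had adjusted p = 0.121 with an estimated correlation. Of 24 hypoxia genes 5 were higher and 1 lower (5 and 1 adjusted over the list alone), with BNIP3L (0.84 ± 0.08) and NDRG1 (0.64 ± 0.08) higher and enolase ENO1 (-0.38 ± 0.07) lower. This list had adjusted p = 0.121 with an estimated correlation. Of 27 mitosis genes 6 were lower and none higher (15 and 0 adjusted over the list alone), including the checkpoint kinase BUB1 (-0.65 ± 0.09), PLK1 (-0.50 ± 0.11), AURKA (-0.39 ± 0.08) and TOP2A (-0.43 ± 0.11). Camera gave this list adjusted p = 0.712 with an estimated correlation. Of 27 interferon response genes DDX60 (-0.64 ± 0.14), IFIT1 (-0.41 ± 0.10) and OAS1 (-0.34 ± 0.08) were lower and none higher (4 and 0 adjusted over the list alone). For these members together camera gave adjusted p = 0.712 with an estimated correlation. Of 22 luminal identity genes 6 were higher and 1 lower (8 and 1 adjusted over the list alone), including AGR2 (0.93 ± 0.11) and CDH1 (0.58 ± 0.08). The list test had adjusted p = 0.734 with an estimated correlation. The estrogen-induced list did not pass, with 2 of 47 higher and 8 lower (2 and 9 adjusted over the list alone), among the latter CA12, SLC7A5 and BCL2 (-0.75 ± 0.09). The basal and mesenchymal list did not pass, with 5 of 18 higher (5 adjusted over the list alone), among them CD44 (1.24 ± 0.08) and caveolin CAV1 (0.54 ± 0.08). Without MCF7-F ethanol replicate 1 TOP2A (adjusted p 0.224), DDX60 (0.142), IFIT1 (0.21) and ENO1 (0.0732) did not pass. PLK1 (0.108) and AURKA (0.0904) did not without MCF7-G ethanol replicate 2, nor OAS1 (0.157) without MCF7-G ethanol replicate 1. In all 1732 genes passed, 1311 higher and 421 lower in MCF7-G. Of 262 small RNAs 32 were higher and 3 lower, and 75.7% of all calls were higher as deposited against 63.2% after quantile normalization. The count was 671 without MCF7-F ethanol replicate 1, 741 without MCF7-G ethanol replicate 1 and 1130 without MCF7-G ethanol replicate 2.

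The exposed lines also differed from each other in ethanol. Against MCF7-G, MCF7-B had more of the collagen chaperone FKBP10 (1.88 ± 0.08, adjusted p = 6.35e-07), CEACAM6 (1.85 ± 0.11), netrin 4 (NTN4, 1.69 ± 0.10), CP (1.55 ± 0.10), CEACAM5 (1.497 ± 0.16), cystatin A (CSTA, 1.49 ± 0.11), EPAS1 (1.36 ± 0.10) and SLC7A5 (1.31 ± 0.13). It had less PLS3 (-2.54 ± 0.12), AGR3 (-2.13 ± 0.21), KLHL4 (-2.06 ± 0.10), PCDH10 (-1.72 ± 0.11), ST8SIA4 (-1.63 ± 0.13), FSTL5 (-1.51 ± 0.11), NPNT (-1.499 ± 0.10) and BRINP3 (-1.49 ± 0.13). ESR1 was lower in MCF7-B (-0.34 ± 0.08, adjusted p = 0.0384, and 0.306 without MCF7-B ethanol replicate 2), and none of the other 9 genes reported in every comparison passed. With the preset correlation 7 lists passed, all higher in MCF7-B, and none passed with an estimated one. Of 27 S phase genes 12 were higher and none lower (20 and 0 adjusted over the list alone), including the ribonucleotide reductase subunit RRM2 (0.71 ± 0.08), MCM6 (0.77 ± 0.09), MCM4 (0.48 ± 0.07) and CDC6 (0.52 ± 0.08). As a set they had adjusted p = 0.071 with an estimated correlation. Of 26 ribosome biogenesis genes 5 were higher and none lower (10 and 0 adjusted over the list alone), including NOLC1 (0.48 ± 0.09), and of 24 hypoxia genes 5 were higher and 2 lower (11 and 2 adjusted over the list alone), including PDK1 (0.63 ± 0.09) and ERO1A (0.62 ± 0.10) higher and BNIP3L (-0.47 ± 0.08) lower. Each of these 2 lists had adjusted p = 0.071 with an estimated correlation. Of 27 interferon response genes 8 were higher and none lower (11 and 0 adjusted over the list alone), including IFIT1 (0.97 ± 0.10), DDX60 (0.99 ± 0.14), OAS1 (0.60 ± 0.08) and OAS3 (0.60 ± 0.08). This list had adjusted p = 0.114 with an estimated correlation. Of 27 mitosis genes 4 were higher and none lower (11 and 0 adjusted over the list alone), including BUB1 (0.52 ± 0.09) and CENPA (0.42 ± 0.08). Camera gave this list adjusted p = 0.448 with an estimated correlation. None of 19 NRF2 targets and metallothioneins passed (3 higher adjusted over the list alone), with adjusted p = 0.38 with an estimated correlation, and of 16 heat shock genes HSPD1 (0.47 ± 0.08) and HSPE1 (0.35 ± 0.09) were higher (3 adjusted over the list alone). For these members together camera gave adjusted p = 0.543 with an estimated correlation. Lists that did not pass held single large differences, such as the estradiol hydroxylase CYP1B1 (-1.20 ± 0.11), AGR2 (-1.37 ± 0.11), ERBB4 (-0.91 ± 0.10), CD44 (-0.85 ± 0.08) and TGFBI (0.78 ± 0.09). In all 978 genes passed, 473 higher and 505 lower. The count was 371 and 382 without MCF7-B ethanol replicate 1 and 2, 454 and 442 without MCF7-G ethanol replicate 1 and 2, and 542 with centred arrays. Without MCF7-G ethanol replicate 2 HSPE1 (adjusted p 0.296), BUB1 (0.0835) and HSPD1 (0.0553) did not pass, without MCF7-B ethanol replicate 1 CENPA (0.0955) and NOLC1 (0.0959) did not, nor BNIP3L (0.0521) without MCF7-G ethanol replicate 1.

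The 2 exposed lines shared many of their differences from MCF7-F. Both comparisons called 670 genes higher and 150 lower, 820 in all, against 74.8 and 8.56 for independent lists, while 26 genes passed in opposite directions. NEB, CT83, IL1R1, AKR1C3 and MUC1 were higher in both and CA12, STC1 and SCML1 lower in both. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.703, where unchanged groups sharing the 2 control arrays gave 0.500 and no shared calls on average. The covariance was 0.0383 against 0.00531 simulated, a difference of 0.0330. The simulated noise was independent across genes and arrays. As the real arrays shared deviations, unchanged groups could give higher values than those simulated. With 1 control array for each comparison, r was 0.546 or 0.554, which no array in common can have made. These r were under 0.703, so part of the excess may come from the shared controls. A single control array on each side also makes the changes less precise, which by itself lowers r, so that part cannot be sized. In the estradiol arrays both comparisons share the MCF7-F estradiol arrays, and no value for unchanged groups was simulated there, so their r of 0.555 and 509 shared genes say little on their own. Between treatments, again with no array in common, r was 0.230 for MCF7-B in ethanol and MCF7-G in estradiol (500 genes shared, 39 opposite) and 0.416 for MCF7-B in estradiol and MCF7-G in ethanol (482 shared, 33 opposite). Over all genes 43.5% and 57.2% had the same sign in these pairs. In ethanol, where both comparisons share the MCF7-F arrays, 77.6% did, against 66.7% for simulated unchanged groups. The 43.5% is under an even split, and whether deviations shared between arrays pull these shares was not tested.

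Genes called with estradiol in 1 line were compared between the other 2 lines in ethanol, and 1 of the 6 sets had p under 0.05 with an estimated correlation. The p-values of these sets were not adjusted over the 6 sets, unlike those of the gene lists. The 64 genes that fell with estradiol in MCF7-B were higher in MCF7-G than in MCF7-F in ethanol, by a median of 0.44, with 41 of them past the threshold upward and 2 downward (camera p = 9.33e-32, p = 0.0187 with an estimated correlation). The 151 genes that rose in MCF7-B had a median of -0.00255 there, with 21 higher and 19 lower (p = 0.862 with an estimated correlation). Between MCF7-B and MCF7-F, the 177 genes falling in MCF7-G had a median of 0.23, with 67 higher and 14 lower (p = 0.17 with an estimated correlation), and the 214 rising in MCF7-G had a median of 0.07, with 35 higher and 16 lower (p = 0.369 with an estimated correlation). Between MCF7-B and MCF7-G, the 402 genes rising in MCF7-F had a median of 0.08, with 41 higher and 17 lower (p = 0.295 with an estimated correlation), and the 59 falling had a median of -0.16, with 4 higher and 14 lower (p = 0.0928 with an estimated correlation).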

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

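No test in this part was chosen after the result was seen. SYTL5 stood out because its estradiol response differed between MCF7-B and MCF7-F, by -1.26 ± 0.12 (adjusted p = 0.0109), and between MCF7-G and MCF7-F, by -1.09 ± 0.12 (adjusted p = 0.0471). Its level without estradiol was already higher in MCF7-B and MCF7-G, at means of 7.34 and 6.95 against 6.002 in MCF7-F, and with estradiol the means were 7.39, 7.17 and 7.31. CALCR stood out because its response differed between MCF7-B and MCF7-G, by -1.08 ± 0.12 (adjusted p = 0.0338). Its means in ethanol were 5.18 in MCF7-B and 5.34 in MCF7-G, and in estradiol 5.05 and 6.30, while MCF7-F went from 5.51 to 6.17. The adjusted p of SYTL5 was 0.12 in the first difference without MCF7-F ethanol replicate 1 and 0.477 in the second without MCF7-G estradiol replicate 1, and that of CALCR was 0.376 without the latter array. None of these 3 calls held with centred arrays or with every probe set tested, where 1 other probe set passed, upward, in MCF7-G minus MCF7-F, and no biological explanation was tested for either gene.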

How the results depend on the processing

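The gene classes, the estradiol arrays and the further settings for the list and shared-call results were chosen after seeing the data, and the other alternatives were planned. Of 430 named gene results past the threshold 251 stayed past it under every alternative run, 313 under every alternative that keeps all arrays, and none changed sign. At least 1 left-out array ended 178, testing every probe set 101, centring 76, only the groups compared 37, quantile normalization 17, the mean of probe sets 2, leaving out small RNAs 1, and the other prior 1. Of 81 list calls 12 held with an estimated correlation and 69 did not. Counts that moved by over 1.5 times are given next, with the cause not tested unless fewer arrays or a stricter or looser threshold made it. Requiring a fold of 1.5 gave 205, 92, 168 and 119 genes for estradiol in MCF7-F, MCF7-B, MCF7-G and on average, and 507, 523 and 302 for MCF7-B against MCF7-F, MCF7-G against MCF7-F and MCF7-B against MCF7-G. Adjusted p 0.1 gave 601 for estradiol in MCF7-G, 2698 for MCF7-B against MCF7-F, 1476 for MCF7-B against MCF7-G and 40 falling in all 3 lines. Centring gave 303, 87 and 187 for estradiol in MCF7-F, MCF7-B and MCF7-G, 542 for MCF7-B against MCF7-G, 51 rising and 9 falling in all 3 lines. Only the groups compared gave 802 and 73 for estradiol in MCF7-F and MCF7-B, with 52 rising and 13 falling in all 3. Every probe set gave 103 and 258 for MCF7-B and MCF7-G, with 65 rising and 13 falling in all 3, and quantile normalization gave 39 falling in all 3. The 1 gene of each difference between responses became 0 for MCF7-B minus MCF7-F with every probe set, centring and only the groups compared and 2 with only genes above the median of gene means. It became 0 with centring and 2 with quantile normalization for MCF7-G minus MCF7-F. For MCF7-B minus MCF7-G it became 0 with every probe set, genes above that median, centring, quantile normalization, the other prior and only the groups compared. Beside these counts of 0 from limma, unadjusted p was under 0.05 for 1290, 2175 and 334 genes in the model as planned. Independent noise would give 1123 in each, which is no sure chance level given the deviations shared between arrays described below. The estradiol arrays gave 1101 for MCF7-B against MCF7-F. The 820 genes shared by MCF7-B and MCF7-G became 370 and 362 with 1 control array each, 509 in estradiol, 500 with MCF7-G in estradiol and 482 with MCF7-B in estradiol. With each array left out the counts ranged over 141 to 659, 61 to 246 and 112 to 590 for estradiol in MCF7-F, MCF7-B and MCF7-G, 597 to 2465, 671 to 2429 and 371 to 1432 for the line comparisons in the order above, 0 to 1 for each difference between responses, and 38 to 135 rising and 7 to 27 falling in all 3. A lone array was assumed to vary like the other groups. In the same runs the medians of genes called in another line ranged from 0.0417 to 0.130 (MCF7-F rising, MCF7-B against MCF7-G), 0.0109 to 0.0970 (MCF7-G rising, MCF7-B against MCF7-F), -0.0530 to 0.0292 (MCF7-B rising, MCF7-G minus MCF7-F), -0.0258 to 0.168 and -0.116 to 0.00749 (MCF7-F falling and rising, MCF7-B minus MCF7-G) and -0.200 to -0.00283 (MCF7-G falling, MCF7-B minus MCF7-F). List medians changed sign under quantile normalization for cholesterol synthesis (-0.000788) and ribosomal proteins (-0.00773) with estradiol in MCF7-F and for ribosomal proteins in both differences from MCF7-F (0.00981 and 0.00935). With an array left out they ranged over -0.0381 to 0.204 (NRF2 targets) and -0.0198 to 0.178 (histones) with estradiol in MCF7-F and over -0.141 to 0.00482 (immediate early genes) in MCF7-B minus MCF7-F. Same-numbered replicates deviated together in 7 of 15 pairs of groups (r above 0.1) and oppositely in 7 (r under -0.1), so the numbers were not taken to pair arrays. These signs were not scattered. The replicate differences of MCF7-F estradiol, MCF7-G ethanol and both MCF7-B groups correlated with each other (r from 0.369 to 0.516). Those of MCF7-F ethanol and MCF7-G estradiol also did (0.294) and ran against the other groups (-0.137 to -0.337, but 0.0138 for MCF7-B and MCF7-G in estradiol). Deviations shared between arrays were thus left unmodelled, and no other pairing was run. With the replicate block the higher and lower counts were 470 and 86, 187 and 66, 256 and 211, and 828 and 593 for estradiol in MCF7-F, MCF7-B, MCF7-G and on average, 1508 and 609, 1442 and 563, and 584 and 587 for the line comparisons, and 1 gene for each difference between responses, and none of the 430 named results was lost. Logs of values plus a pseudocount were not run, as the values were log2 already.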

Other observations

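Of the tests in this part, the one on neighbouring genes and the exchange of treatment labels were set before their results were seen, while the line comparisons in the estradiol arrays and the tests on the MCF7-F ethanol arrays, on chromosome 5 and on estrogen receptor activity were chosen only after the result was seen, as was the rule that a bound must hold on all arrays while the values with each array left out need only stay outside the range of the opposite outcome.

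The lines also differed when compared in the estradiol arrays. Of 27 mitosis genes 13 were lower in MCF7-G than in MCF7-F and none higher (25 and 0 adjusted over the list alone, adjusted p = 0.216 with an estimated correlation), with BUB1 at -0.92 ± 0.09, PLK1 at -0.74 ± 0.11 and AURKA at -0.53 ± 0.08, and 6 of 27 S phase genes were lower and none higher (8 and 0 adjusted over the list alone, adjusted p = 0.216 with an estimated correlation). Against MCF7-G, MCF7-B had 13 of 27 mitosis genes higher (20 adjusted over the list alone, adjusted p = 0.153 with an estimated correlation). It had 12 of 27 S phase genes higher (19 adjusted over the list alone, adjusted p = 0.0745 with an estimated correlation), with RRM2 at 0.81 ± 0.08 and MCM6 at 0.84 ± 0.09, and 9 of 27 interferon response genes higher (13 adjusted over the list alone, adjusted p = 0.109 with an estimated correlation), with IFIT1 at 0.88 ± 0.10. Against MCF7-F, MCF7-B kept a called shift of hypoxia genes, 7 of 24 higher and 1 lower (12 and 2 adjusted over the list alone, adjusted p = 0.0187 with an estimated correlation), with NDRG1 at 0.67 ± 0.08 and ERO1A at 0.84 ± 0.10. The xenobiotic genes were called too, 7 of 38 higher and 4 lower (14 and 5 adjusted over the list alone, adjusted p = 0.0442 with an estimated correlation), with AKR1C3 at 1.30 ± 0.10. Of 47 estrogen-induced genes 1 was higher and 9 lower in MCF7-B than in MCF7-F (3 and 12 adjusted over the list alone, median -0.145). In MCF7-G 2 were higher and 8 lower than in MCF7-F (2 and 12 adjusted over the list alone, median -0.107). With camera this list passed with the preset correlation in both, but had adjusted p = 0.305 and 0.222 with an estimated correlation. ESR1 was lower in MCF7-B than in MCF7-F by 0.45 on the log2 scale in these arrays as well (adjusted p = 0.00761).

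The first pattern is the large number of genes between the exposed lines and MCF7-F in ethanol, mostly higher, beside MCF7-F ethanol arrays with low small RNA values. In the estradiol arrays 94.0% of the MCF7-B calls and 92.1% of the MCF7-G calls had the same direction (91.2% and 90.5% at the least with 1 array left out), which argues against those 2 arrays as the whole source of the calls. The changes were smaller there, with a median ratio of 0.711 and 0.650 to those in ethanol, and 812 of 1739 and 817 of 1732 calls passed in both, so part may come from those arrays. After the median change of the 40 nearest expressed genes was taken off, 66.8% of the MCF7-B calls and 73.3% of the MCF7-G calls stayed past the threshold, which argues against shifts shared by neighbouring genes as their whole source. After this step 1039 genes were called higher and 833 lower in MCF7-B, against 1282 and 457 before. In MCF7-G they were 1084 and 668, against 1311 and 421. Such shifts may therefore make part of the excess of higher calls. The excess of higher calls is another matter. In the estradiol arrays 53.7% of MCF7-B calls and 44.2% of MCF7-G calls were higher. Both shares were near the even split that MCF7-F ethanol arrays standing apart would give. With 1 array left out the observed shares ranged over 42.6% to 64.2% and 44.4% to 65.8%, so neither is firm. The excess may come from the MCF7-F ethanol arrays, but in neither line can those arrays and the lines be told apart. The chronic exposure was not tested for any of these calls. As each exposure had a single subline, it cannot be told apart from other differences between the sublines.

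The second pattern is regional. Of 19 windows of 40 neighbouring genes on chromosome 5, 12 were higher in MCF7-B than in MCF7-F in ethanol beyond a bound from 200 permutations of gene order, and 12 were in MCF7-G, out of 463 windows of which 59 and 44 lay beyond their bounds. In the estradiol arrays the median of 406 chromosome 5 genes lay above that of other genes by 0.11 in MCF7-G (0.11 to 0.13 with 1 array left out) and by 0.12 in MCF7-B (0.07 to 0.22), which argues against the MCF7-F ethanol arrays as the whole source, less firmly in MCF7-B, where the lowest value was under the bound of 0.1 though above the 0.05 that those arrays would give. A candidate explanation is a difference in chromosome 5 dose between the lines, as 72.7% of those genes in MCF7-B (66.5% to 72.4% with 1 array left out) and 71.4% in MCF7-G (69.95% to 74.1%) lay above the median of the other genes, so the 70% set for a dose difference was not reached with every array left out. DNA was not measured here, and chromosomes 14 and 18 were also shifted in MCF7-B in ethanol, by 0.15 each, so growth of a subclone during culture and the exposure itself both stay open.

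The third pattern is the higher level in MCF7-G than in MCF7-F of the 64 genes that fell with estradiol in MCF7-B. In the estradiol arrays their median lay above that of all genes by 0.21 (0.20 to 0.28 with 1 array left out), so a smaller shift was also seen without the MCF7-F ethanol arrays. In ethanol their own median was 0.44, with -0.0333 for all genes, so the shift was larger there. In the estradiol arrays members varied by more than 0.21 (median absolute deviation 0.38). For each gene the drop is the difference between its responses in MCF7-G and MCF7-F, given above, so it adds no separate evidence on the arrays. How much of the shift comes from the MCF7-F ethanol arrays therefore cannot be told. Less estrogen receptor activity in MCF7-G without added estradiol might raise such genes, and it would also lower the genes that rise with estradiol. These had a median of -0.00255 in MCF7-G against MCF7-F, but members went both ways (median absolute deviation 0.29), so this explanation cannot be told apart from others that act on the falling genes alone, including the exposure to genistein, which was not tested.

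Estradiol and ethanol labels were exchanged within lines in 100 drawn of the 108 distinct ways, the real one included. The real labels gave 1244 genes averaged over the lines, the highest of the other splits gave 70, and 1 of the 100 splits gave as many, which was the real one. This argues against chance assignment of the labels for this count. In exchanged splits the estradiol effect adds to the spread within groups and lowers their counts, so 1244 against 70 overstates the contrast. As the replicates may be technical, the exchange does not measure variation between cultures.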
